A study of Mus musculus with 2 samples.

How the data were processed

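RNA was measured in primary hepatocytes of C57BL/6 mice that had been infected, at a multiplicity of infection of 40, with an adenovirus carrying a short hairpin RNA against Setdb2 (shSETDB2) or a control hairpin (shControl). Per the labels' protocols, infection lasted 48 h in medium with 2% serum and 10 nM dexamethasone, a synthetic glucocorticoid, and was followed by 24 h without serum and 4 h with 1 µM dexamethasone. Stranded libraries were made from 1 µg of total RNA depleted of ribosomal RNA, per the labels. Each group holds 1 library, made from a pool of 3 mice per the file headers. Whether the same mice gave both pools is not given in the sources used here.

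The authors aligned reads with TopHat2 2.0.12 and quantified transcripts with Cufflinks 2.2.1 on the mm10 genome, per the submitters' processing notes. The annotation release, the strand setting and any scaling between the libraries are not given in the sources used here. The deposited FPKM values (fragments scaled to transcript length and to the number of mapped fragments) are listed per RefSeq transcript, per the file headers, for 33308 transcript rows. The authors' table also gives a log2 fold change, a p-value and a q-value per transcript, and a yes or no for a q-value under 0.05. In the deposited fold change column, 2099 cells read as a spreadsheet error. 1 line of the table was emptied for this work and is not analysed here.

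The fixed plan had assumed gene rows. Since the table holds transcripts, FPKM values were summed per gene symbol, which gave 23907 genes, 18872 of them on a single row. A spreadsheet date stood in place of the symbol in 53 rows, and all 53 were restored from the RefSeq accession. In 569 rows the accession carried a copy number, so these transcripts map to more than 1 place. Gene coordinates come from GENCODE mouse release M21, whose assembly is that of mm10.

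With 1 library per group, no test over replicates was possible, and no p-value was computed. Ratios were computed as log2((shSETDB2 + 0.1)/(shControl + 0.1)), with a pseudocount of 0.1 FPKM. Folds are on this scale and understate the difference of low genes. The exceptions are the folds of single Insig2 transcripts, which are plain ratios of FPKM, and those of the counting intervals described below. Genes at 1 FPKM or more in at least 1 library were analysed, and those at least 2-fold higher or lower were counted. The authors' calls at a q-value under 0.05 were counted from the deposited table as theirs.

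For 23 gene lists and 6 lists of cell type markers, members at least 1.5-fold higher or lower were counted. The median log2 ratio of each list was placed among those of 10000 random lists of the same size, matched on mean expression in 20 bins. A list was said to stand apart in the outermost 2.5% on either side. This describes the 2 libraries and is no test of the conditions. The 29 lists are cholesterol synthesis, fatty acid synthesis, regulation of sterol regulatory element-binding proteins (SREBP), glucocorticoid receptor targets, gluconeogenesis, fatty acid oxidation, bile acids, LXR targets, xenobiotic metabolism, urea cycle and amino acid catabolism, secreted hepatocyte proteins, acute phase, interferon, NF-kB, p53, cell cycle, unfolded protein response, NRF2, H3K9 methylation, circadian clock, cytoskeleton and matrix, mitochondrial mRNAs, immediate early genes, and markers of macrophages, sinusoidal endothelial cells, stellate cells, cholangiocytes, lymphocytes with neutrophils, and erythroid cells. Insig2 was put on the list of glucocorticoid receptor targets from what is known of the study. That list shares measured members with those of fatty acid synthesis, SREBP, gluconeogenesis, fatty acid oxidation, urea cycle, acute phase, NF-kB, p53 and circadian clock. The gluconeogenesis and urea cycle lists share Tat, and the unfolded protein and immediate early lists share Atf3. Lists that share genes are not independent.

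Named genes followed a rule. It took Setdb2, Insig2 and Nr3c1 whatever their values. It took the 15 highest and the 15 lowest log2 ratios among genes at 5 FPKM or more in the higher library, leaving out predicted genes, small RNAs and symbols on more than 1 row, which left 6202 of 8681 genes. It also took up to 4 members per list with the largest absolute ratio, and up to 8 for the cholesterol, fatty acid, SREBP and glucocorticoid receptor lists. Some genes that the rule names are not reported here. The lists, the rule, the thresholds and most alternatives were fixed before the data were examined.

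The low values step in near-multiples of a single fragment, which gave the depth. By these steps, 1 fragment on a transcript of 1000 nt was worth 0.0235 FPKM in shControl and 0.0223 FPKM in shSETDB2. That is about 51300000 and 53500000 fragments, if no scaling between the libraries was applied, which is not given in the sources. Of the low values, 76.5% and 78.9% lay within 20% of a step of a whole multiple. Exact binomial intervals at 95% were made from the fragment numbers this implies. No pseudocount enters these intervals, so they are on another scale than the ratios beside them. The intervals rest on approximate transcript lengths and cover counting error only, not the difference between cultures.

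The calculations were tested on simulated data for the 11707 genes analysed. Of lists of 20 genes drawn at random and shifted by a log2 amount of 0.3, 0.6 and 1, 39%, 92.5% and 100% stood apart. Of unshifted lists, 4% did, a rate that need not hold for genes that vary together. Of 200 genes given a 2.5-fold difference with counting noise, 98.5% passed 2-fold, and of 200 given a 1.5-fold difference, 1%. Alternatives were other pseudocounts, other filters, centring on the median, rescaling without the 100 highest genes, leaving out predicted genes and small RNAs, unmatched random lists, the mean of members, and a stricter use of the authors' calls. Single transcript rows, leaving out genes listed at 0, centring in bins of GC content and length, rescaling over the genes as deposited at 1 FPKM or more, and 2 reduced glucocorticoid receptor lists were added after the data were seen. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.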

Results

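The transcriptomes of dexamethasone-treated mouse hepatocytes with and without knockdown of Setdb2 were compared. Setdb2 is a member of a family of histone H3 lysine 9 methyltransferases. The question was which known glucocorticoid receptor targets and lipid genes differ with its knockdown. Both libraries had dexamethasone, so no gene's response to it was measured. Each group was measured in 1 library from a pool of 3 mice, so that no difference given here has a replicate check. By the steps of low values, the libraries held about 51300000 (shControl) and 53500000 (shSETDB2) fragments, if no scaling between them was applied. At 1 FPKM or more there were 11435 genes in shControl and 11143 in shSETDB2, and 11707 in at least 1 of them. Small RNAs made up 56.5% of the summed FPKM in shControl and 49.6% in shSETDB2.

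Setdb2 was listed at 7.13 FPKM in shControl and 1.94 FPKM in shSETDB2, 3.55-fold lower (log2 ratio -1.83, 95% counting interval -2.06 to -1.69). The gene lies on the minus strand of chromosome 14 from 59402009 to 59440884 (mm10). Insig2, which encodes a protein of the endoplasmic reticulum that retains SREBP precursors, was 3.30-fold lower, at 61.1 FPKM in shControl and 18.4 FPKM in shSETDB2. It lies on the minus strand of chromosome 1 from 121304353 to 121332589. The transcript NM_178082, with its first base at 121332589, was 3.55-fold lower (41.9 and 11.8 FPKM). NM_133748, which begins at 121328024, was 2.93-fold lower (16.6 and 5.67 FPKM). NM_001271531 was listed at 2.28 and 0.913 FPKM, with a q-value of 0.170 in the authors' deposited table. Nr3c1, the glucocorticoid receptor gene, was listed at 21.6 and 14.8 FPKM (log2 ratio -0.54).

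**Figure D1:**
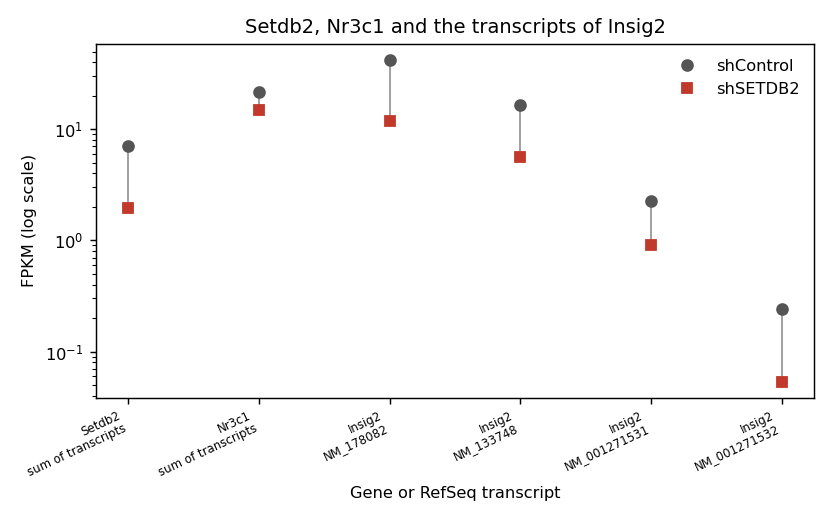
FPKM (log scale) of Setdb2 and Nr3c1, each summed over transcripts, and of the 4 listed transcripts of Insig2; circles are the shControl library and squares the shSETDB2 library, 1 pool each. Setdb2 stood at 7.13 and 1.94 FPKM, and each Insig2 transcript was lower in shSETDB2.

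Across the 11707 genes, 1083 (9.25%) were at least 2-fold higher in shSETDB2 and 948 (8.10%) at least 2-fold lower, while 7153 (61.1%) lay within 1.5-fold. The median log2 ratio of all genes was 0.17, and list medians are given below relative to it. With ratios centred on that median, 756 genes were at least 2-fold higher and 1202 lower, so that higher genes made up 38.6% of both in place of 53.3%. With the libraries rescaled without their 100 highest genes, the numbers were 790 and 1210 among the 11607 remaining genes, and 872 and 1825 among the 13110 genes that passed the filter after rescaling. Genes under 1 FPKM in both libraries were mostly lower in shSETDB2: leaving out predicted genes and small RNAs, 79.6% of those at 0.03 to 0.1 FPKM in the higher library were, 85.9% of those at 0.1 to 0.3 FPKM and 72.7% of those at 0.3 to 1 FPKM.

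Among the named genes with the highest ratios, Serpina5, a serine protease inhibitor, was 29.5-fold higher in shSETDB2 (1.46 and 45.9 FPKM), the chemokine gene Cxcl13 17.7-fold (4.88 and 87.8 FPKM) and Pparg2 19.9-fold (0.680 and 15.4 FPKM). Scn7a, Tnfsf18, Zfyve28 and Rec8 went from under 0.4 FPKM to 15.2, 26.2, 14.9 and 13.1 FPKM. Foxj1, Ltbp2, Akr1c20, Selenbp2, Bmf and Cml2 were 11.6-fold to 17.1-fold higher.

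Among those with the lowest ratios, Cyp2b10, a cytochrome P450 induced through the receptor CAR, was 23.6-fold lower (37.4 and 1.49 FPKM). Adm, which encodes adrenomedullin, was 13.7-fold lower (82.1 and 5.90 FPKM), and Arg1, the arginase of the urea cycle, 13.3-fold (15.2 and 1.06 FPKM). The heat shock genes Hspa1a and Hspa1b were listed at 26.5 and 40.8 FPKM in shControl and at 0.712 and 3.04 FPKM in shSETDB2. Il1f9, Gas1, Mt3, Krt5, Il7 and Ces1d were 12.9-fold to 78.9-fold lower. Gpx2, which overlaps Fntb, was listed at 20.4 and 0.127 FPKM, and Slc10a4 at 5.23 and 0.0388 FPKM. In the authors' deposited table the q-values of these last genes were 0.0305 and 0.157. H2-M9 and H2-Q2 were 35.4-fold and 25.8-fold lower. Reads of the H2 genes, of Hspa1a and Hspa1b, and of the Ces1 and Selenbp genes can be shared with close paralogs, so that their values are uncertain.

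**Figure D2:**
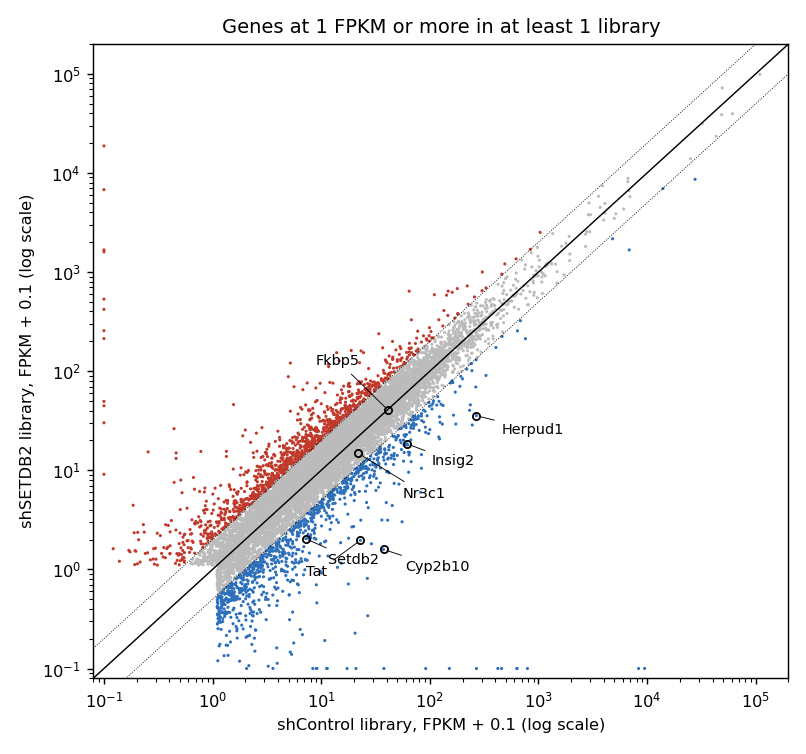
FPKM + 0.1 of each gene in the shControl library (horizontal, log scale) and the shSETDB2 library (vertical, log scale) for genes at 1 FPKM or more in at least 1 library; dotted lines mark 2-fold. The 1083 genes at least 2-fold higher are red, the 948 at least 2-fold lower are blue, and points at the axis floor of 0.1 are listed at 0 in 1 library.

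Glucocorticoid receptor targets were lower as a group in shSETDB2. Of 32 measured members, 12 were at least 1.5-fold lower, 3 at least 1.5-fold higher and 17 in between. The members named here are those with the largest ratios. Tat, the aminotransferase that is a classic glucocorticoid-induced gene, was 11.7-fold lower (22.8 and 1.86 FPKM), and Igfbp1 was 3.63-fold lower (329 and 90.4 FPKM). Klf9, Angptl4 and Tsc22d3, the last encoding the glucocorticoid-induced leucine zipper, were 2.75-fold, 2.60-fold and 2.27-fold lower. Tdo2, a tryptophan dioxygenase gene, was 4.16-fold higher (17.7 and 74.0 FPKM), and Pik3r1 3.19-fold. The median log2 ratio of the list was -0.20, which lay -0.37 from that of all genes, at percentile 0.08 of the random lists. Without Insig2 the percentile was 0.21, and without the 3 lowest members 0.27. Gluconeogenesis genes, of which 2 measured members, Tat and Got1, are also on that list, did not stand apart (percentile 6.11, with 1 of 14 higher and 2 lower). There Gpt was 2.67-fold lower and Gpt2 2.10-fold higher. Pck1, G6pc and Sds, which are on both lists, did not reach 1 FPKM in either library. Nor did Ppargc1a of the gluconeogenesis list, so the list results cover none of these genes.

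**Figure D3:**
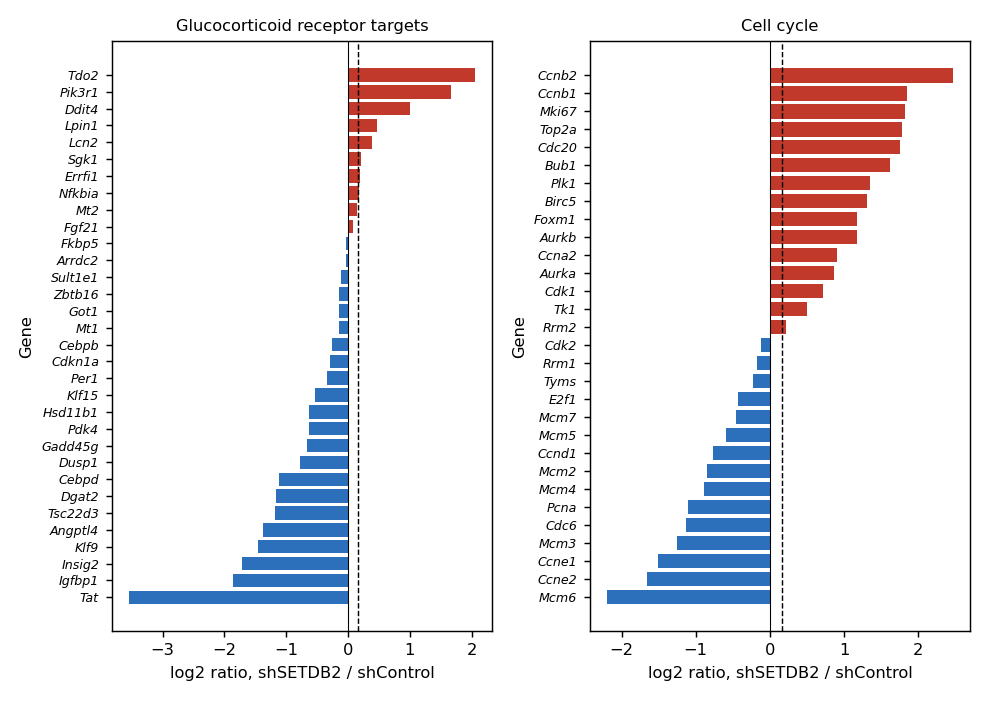
Log2 ratio of shSETDB2 over shControl (horizontal) of the 32 glucocorticoid receptor targets and the 30 cell cycle genes at 1 FPKM or more; each bar is 1 gene, from 1 library per group, and the dashed line is the median of all genes, 0.17. Tat is the lowest of the first list, and cyclin B genes and Mcm6 mark the ends of the second.

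The lipid synthesis lists did not stand apart. Of 24 genes of cholesterol synthesis and uptake, 3 were at least 1.5-fold higher and 3 lower (percentile 19.5). Nsdhl was 2.70-fold and Hmgcs1 2.46-fold higher, while Idi1, Stard4 and Sqle were 2.61-fold, 1.95-fold and 1.67-fold lower. Sc5d had a log2 ratio of -0.48. Of 23 genes of fatty acid and triglyceride synthesis, 8 were higher and 4 lower (percentile 95.3). Scd1, a fatty acid desaturase gene, was listed at 64.8 and 145 FPKM and Acaca at 4.46 and 9.60 FPKM. Fads2 was 1.68-fold higher, and Elovl5, Dgat2, Elovl6 and Thrsp were 3.12-fold, 2.24-fold, 2.02-fold and 1.66-fold lower. On the SREBP list, 4 of 12 genes were higher and 1, Insig2, lower (percentile 68.4). Srebf1 was listed at 20.4 and 37.9 FPKM. Rnf145, Mbtps1 and Rnf139 were 3.78-fold, 2.18-fold and 1.79-fold higher, and Insig1 had a log2 ratio of -0.31.

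Fatty acid oxidation and ketogenesis genes were higher as a group, with 14 of 28 at least 1.5-fold higher and 4 lower. Cd36, a fatty acid transporter gene, was listed at 45.2 and 199 FPKM and Acads at 38.8 and 85.1 FPKM, whereas Acot2 was 4.16-fold lower. The median lay 0.40 above that of all genes, at percentile 99.9. LXR targets and lipoprotein genes held 6 higher and 0 lower of 15 (percentile 91.4), among them Lipc, Pltp, Lrp1 and Mttp at 2.26-fold to 3.39-fold. Of 14 bile acid genes, 2 were higher and 5 lower (percentile 2.61). Nr0b2, Abcc2, Abcg5 and Abcg8 were 3.03-fold, 2.94-fold, 2.66-fold and 2.37-fold lower.

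The fixed lists of xenobiotic metabolism and amino acid catabolism were lower as groups. Of 22 genes on the fixed xenobiotic list, 14 were lower and 6 higher, with a median -0.90 from that of all genes (percentile 0). Gsta1 was 5.93-fold lower, and Cyp1b1 was 9.56-fold higher from 0.108 FPKM. Cyp2a4, listed at 3.83 and 0.0129 FPKM, can share reads with a close paralog, and its q-value in the authors' deposited table was 0.302. By symbol, a grouping made after the data were seen, 19 of 39 Cyp genes were higher and 11 lower, and 7 of 11 Ugt genes higher and 2 lower, with medians 0.31 and 0.71 above that of all genes. Of 22 genes of the urea cycle and amino acid catabolism, 9 were lower and 6 higher (median -0.49 from all genes, percentile 0.11). Among them, Tat and Tdo2 are also glucocorticoid receptor targets. Gldc, of the glycine cleavage system, was 5.93-fold lower (123 and 20.6 FPKM). The percentile of this list was 2.96 with no filter on low values, where it no longer stood apart.

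Stress response genes were lower in shSETDB2. Of 26 genes of the unfolded protein and integrated stress response, 19 were at least 1.5-fold lower and 0 higher. Herpud1, which acts in degradation of proteins from the endoplasmic reticulum, was 7.52-fold lower (267 and 35.5 FPKM). The transcription factor gene Atf3 was 3.84-fold lower, Phgdh 3.19-fold and Sdf2l1 2.86-fold. The median lay -1.11 from that of all genes (percentile 0). Of 20 NRF2 and oxidative stress genes, 8 were lower and 1 higher (median -0.54 from all genes, percentile 0.01). Srxn1 was listed at 759 and 213 FPKM, Slc7a11 at 91.5 and 24.0 FPKM and Gsta4 at 105 and 41.4 FPKM.

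Markers of other liver cells were lower too. All 10 measured Kupffer cell and macrophage markers and all 13 sinusoidal endothelial markers were at least 1.5-fold lower, with medians -1.75 and -1.53 from that of all genes (percentiles 0.01 and 0.02). Cd5l, Cd68, Marco and C1qa were 6.73-fold, 4.39-fold, 4.04-fold and 3.74-fold lower, and Lyve1, Gpr182, Bmp2 and Stab2 3.15-fold to 3.97-fold. Some markers, among them Cd5l, Marco, Gpr182 and Bmp2, reached 1 FPKM only in shControl, and such genes can only be lower. Of 14 stellate cell and fibroblast markers, 9 were lower and 0 higher (percentile 0.18), with Colec11, Reln, Pdgfra and Timp1 2.15-fold to 6.22-fold lower. Of these, Colec11, Reln and Pdgfra reached 1 FPKM only in shControl. Pdgfra is a sum of 2 transcripts, listed at 0.699 and 0.437 FPKM and at 0.691 and 0.00864 FPKM in shControl and shSETDB2. Cholangiocyte markers went both ways, with 3 higher and 3 lower of 8 (percentile 89.0). Cldn4 and Pkhd1 were 8.56-fold and 4.97-fold higher, and Krt19 was 3.12-fold lower. Epcam was listed at 1.02 and 0.0197 FPKM, the latter about 2 fragments, with a q-value of 0.0655 in the authors' deposited table. No lymphocyte, neutrophil or erythroid marker reached 1 FPKM, and the table lists none of the mitochondrial mRNAs.

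**Figure D4:**
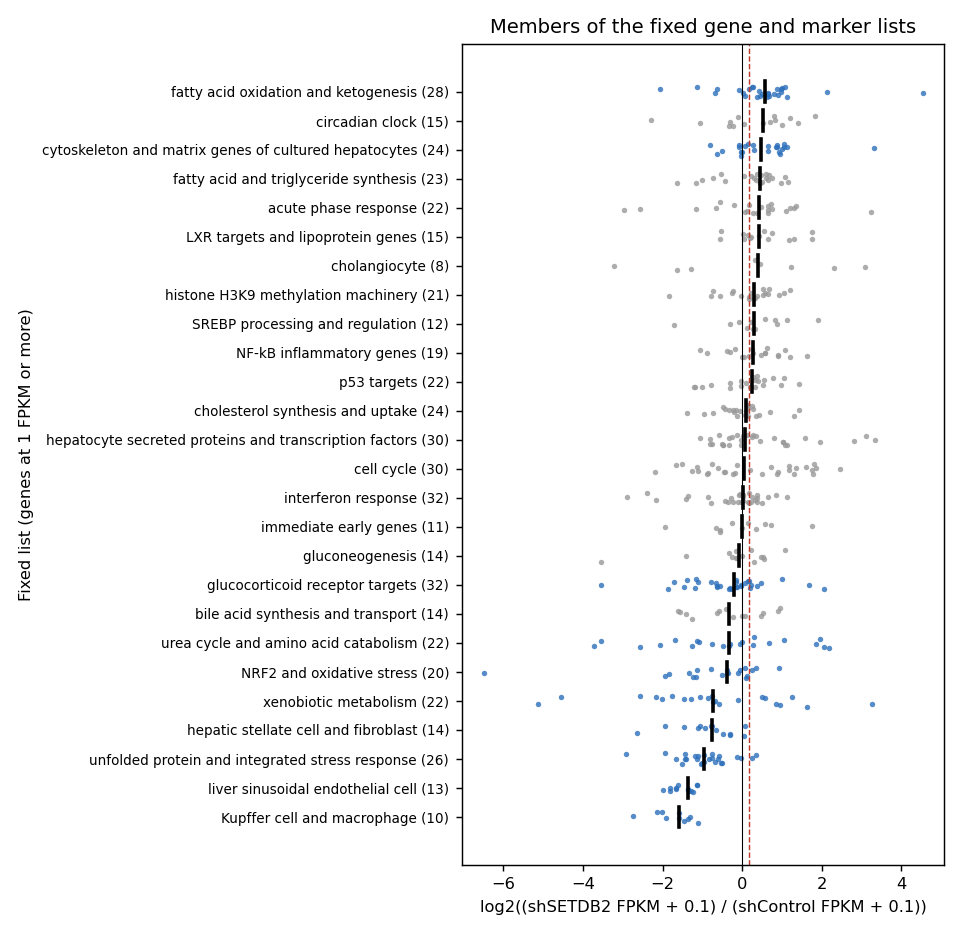
Log2 ratio of shSETDB2 over shControl (horizontal) of the members of each list at 1 FPKM or more (number in parentheses), with the list median as a black bar and the median of all genes, 0.17, as a dashed line; each point is 1 gene. Lists that stood apart from random lists are blue, 8 on the low and 2 on the high side of 26 measured.

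Genes of the cytoskeleton and matrix that cultured hepatocytes express were higher, with 12 of 24 at least 1.5-fold higher and 2 lower (percentile 99.3). Among them, Ctgf, S100a11 and S100a6 were 2.07-fold to 2.18-fold higher. The list did not stand apart by its mean (percentile 86.57), or with libraries rescaled without the 100 highest genes (56.22). That rescaling also takes those 100 genes off the lists, so it does not test scaling alone. Secreted hepatocyte proteins did not stand apart (percentile 26.0, 10 of 30 higher and 4 lower), although Vtn and the fibrinogen genes Fgg, Fga and Fgb were 10.1-fold, 8.69-fold, 7.04-fold and 3.89-fold higher.

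Of 30 cell cycle genes, 13 were higher and 10 lower (percentile 8.72). The cyclin genes Ccnb2 and Ccnb1 were 5.55-fold and 3.60-fold higher and Mki67 3.53-fold, while Mcm6, of the replicative helicase, was 4.59-fold lower (165 and 35.9 FPKM). The circadian list held 7 higher and 2 lower of 15 (percentile 97.1), with Rora, Per2 and Bhlhe40 2.29-fold to 3.56-fold higher and Ciart 4.86-fold lower. Its percentile was 17.51 with a filter of 5 FPKM, and it stood apart under some other alternatives. Acute phase genes were 10 higher and 4 lower of 22 (percentile 97.0). Steap4 and Crp were 9.47-fold and 2.58-fold higher, and Il1rn was 7.79-fold lower. Hamp was listed at 1.92 and 0.241 FPKM, about 24 and 3 fragments, with a 95% counting interval of 2.53-fold to 43.3-fold lower and a q-value of 0.160 in the authors' deposited table. Of 32 interferon response genes, 3 were higher and 7 lower (percentile 9.38), with Rsad2, Mx2, Oasl1 and Isg15 2.65-fold to 7.37-fold lower. On the NF-kB list 6 of 19 were higher and 2 lower (percentile 68.3), with Tnfaip3, Ccl20 and Birc3 2.12-fold to 3.09-fold higher and Cxcl1 2.09-fold lower. Of 22 p53 targets, 4 were higher and 4 lower (percentile 68.3), among them Ei24 and Rrm2b at 2.72-fold and 2.08-fold higher and Pmaip1 and Gdf15 at 2.32-fold and 2.29-fold lower. The H3K9 methylation list holds demethylase genes (Kdm) as well as methyltransferase genes. Of its 21 measured genes, 5 were higher and 3 lower (percentile 78.1). Atrx and the demethylase genes Kdm1a and Kdm4b were 1.92-fold to 2.32-fold higher beside the lower Setdb2. Among 11 immediate early genes 2 were higher and 2 lower (percentile 22.2). Junb and Egr1 were 3.36-fold and 1.65-fold higher, and Zfp36 was 1.57-fold lower.

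The authors' deposited table called 11279 of 16687 transcripts with a p-value under 1 (67.6%), 6864 higher and 4415 lower in shSETDB2. In the authors' deposited table, 5221 of the called transcripts (46.3%) lay within 1.5-fold, and the smallest q-value was 9.991e-05. That test compares 2 pooled libraries, not the conditions over independent cultures.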

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

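Single transcript rows, leaving out genes listed at 0, centring in bins of GC content and length, rescaling over a fixed set of genes, and the reduced glucocorticoid receptor lists were chosen after the data were seen. Of 571 log2 ratios of the 143 named genes under 4 alternatives, 559 stayed on the same side of 1.5-fold, 6 passed it, 6 no longer passed it and 0 reversed. At 2-fold, 33 values no longer passed, 13 of them with a pseudocount of 1, and 2 newly did. Of the 10 lists that stood apart, 8 did so under every alternative tried, the exceptions being the cytoskeleton list and the urea cycle list. Of 288 list values, 272 stayed on the same side. Centring on the median is among these alternatives but cannot move a list's percentile, so its list values are no check. Rescaling applies 1 factor per library, which acts on percentiles only through the pseudocount and the filter. It also leaves the 100 highest genes out of the lists, so its list values are no check of scaling alone. Genes at least 2-fold lower numbered 948, against 588 with a pseudocount of 1, 1825 with rescaled libraries (1210 over a fixed set of genes), 1974 with no filter, and 511 with a filter of 5 FPKM, which tests fewer genes. Higher genes made up 62.5% of both directions with that filter and 38.1% with no filter. The circadian list, at 97.09, went both ways, with percentiles of 17.51 with a filter of 5 FPKM, 78.71 by its mean, 81.12 with a pseudocount of 1, 98.22 with a pseudocount of 0.01, 99.19 rescaled (98.13 over fixed genes), 99.21 with no filter, 98.69 with GC and length bins centred and 97.86 against unmatched lists. Other lists that newly stood apart were the acute phase (98.51, pseudocount 1), immediate early genes (2.24, rescaled), cholangiocyte markers (99.98, filter of 5 FPKM), LXR targets (98.14, GC and length bins centred), bile acids (1.4, unmatched lists) and interferon response (1.58, mean). The cytoskeleton list no longer did when rescaled (56.22, or 55.47 over fixed genes) or by its mean (86.57), nor the urea cycle list with no filter (2.96). For the cytoskeleton list, pseudocounts of 1 and 0.01 gave 99.42 and 99.31. Its move when rescaled therefore points to the genes left out, not to the factor. Apart from the filters and this move, the cause was not tested. Requiring a 2-fold difference left 1554 higher and 1506 lower of the calls in the authors' deposited table. No paired analysis was possible because each group has 1 library. Depth limits low genes most, since 1 fragment on 1000 nt is worth 0.0235 FPKM in shControl.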

Other observations

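Chosen only after their results were seen were the tests of scaling, of gene regulation within cells and of background reads for the cell markers, the depth test and the test on members under 1 FPKM for low genes, and the tests of scaling, of fewer other cells and of the knockdown for the unfolded protein list. Centring in bins of GC content and length was added after the data were seen, with its bounds set before its results, whereas centring on the median and rescaling without the 100 highest genes had been planned as alternatives. Symbol families were also examined only after the data were seen. Of 123 families with at least 10 members at 1 FPKM or more, 11 stood apart on the low side and 13 on the high side of random lists. For lists of unrelated genes, 2.5% on each side is expected. Members of a family can vary together, so that rate need not hold for families. Of 16 Serpina genes, a family that includes secreted liver protease inhibitors, 11 were at least 1.5-fold higher and 0 lower. Their median lay 0.82 above that of all genes. Of 21 H2 genes, of the major histocompatibility complex, 13 were lower and 1 higher, with a median -1.08 from that of all genes. Close paralogs can share reads in both families.

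A hypothesis for the lower macrophage and endothelial markers is that the shSETDB2 pool held fewer of these cells. The test took other macrophage and endothelial genes, none looked at before, of which 9 of 25 and 20 of 28 reached 1 FPKM. Some reached it only in shControl, as Flt1 did (1.20 and 0.252 FPKM), and such genes can only be lower. The median log2 ratio of the 29 genes was -1.15, as fewer of these cells would give. All 20 endothelial genes were at least 1.5-fold lower. Of 9 macrophage genes 7 were lower and 1 higher, Mpeg1, named after its values were seen (6.79 and 12.8 FPKM). A single factor between the libraries moves all genes alike, so the tables argue against it: the median of the fixed markers lay -1.75 from that of all genes. They also argue against reads spread over all genes, since the median marker lost 3.64 FPKM, 100.2 times the 0.0363 FPKM that the median olfactory receptor gene lost. Lower expression within these cells stays open, as the table holds no cell numbers. All 33 of 33 endothelial genes at 1 FPKM or more were at least 1.5-fold lower. Some of them reached 1 FPKM only in shControl and could only be lower, so this count does not decide.

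The cell cycle list split into replication genes, mostly lower, and mitotic genes, mostly higher. A candidate explanation is a different distribution of cycling cells over the cycle. Among genes not looked at before, 11 of 35 S phase genes were at least 1.5-fold lower and 2 higher, while 32 of 41 genes of G2 and mitosis were higher and 1 lower, a difference of medians of -1.83. With bins of GC content and length centred it was -1.80, which argues against those as the whole cause. Fewer endothelial cells and macrophages would lower mitotic genes if those cells were the cycling ones. The mitotic median, however, lay 1.22 above that of all genes. The genes not looked at before repeat the split of the fixed list, which does not tell its cause. An effect of the knockdown was not tested.

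Of 1115 olfactory receptor genes, known for their expression in sensory neurons, 1032 were listed above 0 in shControl and 868 in shSETDB2, with a median of 0.0750 FPKM in shControl and 0.0387 FPKM in shSETDB2. The hypothesis that the shControl library holds more reads spread over all genes, as from genomic DNA, failed the test set for it beforehand: the log2 ratio of the summed FPKM of 73 taste receptor, Mrgpr and crystallin genes was 0.22, where a value below -0.58 had been predicted. That sum was a poor choice, as 4 genes at 1 FPKM or more, outside the pattern, made up 76.0% of it in shControl. Of the 69 genes under 1 FPKM, 64 were not at 0 in both libraries, and 52 of these (81.3%) were lower in shSETDB2. That count was chosen after the first test had failed. It also repeats the pattern of genes under 1 FPKM, which any cause of that pattern would give. The hypothesis may hold and stays open. A smaller depth of shSETDB2 was tested by the ratio of depths from the steps, 1.04. That ratio is the sequenced one only if no scaling between the libraries was applied, which is not given, so it cannot decide.

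For the unfolded protein list, the median log2 ratio was -0.95 as deposited and -0.98 with GC content and length bins centred. As deposited it lay -1.11 from that of all genes, a distance that a single factor between the libraries does not make. Of all macrophage and endothelial genes tested, Pik3ap1 lost the most FPKM (28.8), 6.04% of what Hspa5, the most abundant list member, lost (477 FPKM), which counts against fewer such cells as the source of that loss. With 1 library per group, the knockdown and any other difference between the 2 cultures cannot be told apart.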
